A study of Homo sapiens with 8 samples.

How the data were processed

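RNA was measured on 8 Illumina expression arrays from 2 ovarian cancer cell lines, SK-OV-3 and TOV-21G. Per the labels, cells were transfected with an siRNA against CSE1L or with a scrambled control siRNA, total RNA was extracted after 72 h, and biotin-labelled cRNA was hybridised. Each of the 4 groups held 2 arrays, numbered as experiment 1 and 2. Per the labels and the file headers, the deposited main table held non-normalized bead signal intensity, 1 value per probe and array on a linear scale, and the values showed no sign of subtracted background. Per the file headers, each intensity had a detection p-value beside it, which ranks the probe against the negative control beads of the same array. Per the submitters' processing notes the software was BeadStudio 2. A further deposited table held intensity values normalized by the authors, by a method not given in the sources used here. Within each array its probe order was that of the non-normalized signal (Spearman rho 1).

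The arrays had 24531 probes, of which 21838 carried 1 gene symbol and 2693 carried none in the annotation used here. The latter were tested as themselves, counted and not named as genes. Signals were background corrected by normexp from the detection p-values with an offset of 16, quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was below 0.01 in at least 2 arrays, which kept 10888 probes and dropped 13643. Each gene was represented by its probe with the highest mean over all 8 arrays. That left 9377 genes and probes tested, made of 8373 named genes and 1004 unnamed probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

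limma fitted 4 group means to all 8 arrays with 4 residual and 3.87 prior degrees of freedom. It gave the change after silencing in each line, the mean of both changes, their difference (the TOV-21G change minus the SK-OV-3 change) and the TOV-21G control minus the SK-OV-3 control. Adjusted p-values are from limma with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. SE is the standard error of a log2 change in this fit. Where a gene was undetected on both arrays of 1 group, its fold is given as a lower bound against the lowest detected signal of those arrays. Such a bound holds for the main processing only, and other processing gave smaller folds for many of these genes. For the mean and the difference no fold is given for such a gene. Of 43 gene lists, 41 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. camera with an estimated correlation and fry were run beside it, and CSE1L was left out of every list. Members were also counted with p-values adjusted over the list alone. Such counts do not allow for the choice of lists called on the same data, so they are not further evidence. The groups, comparisons, lists, thresholds, rule for named genes and alternatives were fixed before the data were examined. The p-values measure only the spread between these arrays. The labels give experiment numbers and nothing else about the replicates, so that spread may be technical.

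Genes were named by this rule: CSE1L; in each comparison up to 10 with the largest rise and 10 with the largest fall among symbols past the threshold with the same sign in every same-numbered comparison, filled up to 5 with the smallest p where fewer passed; up to 4 members of each list; RASSF1; and the importin alpha genes. The text gives a selection of the genes this rule took. The experiment numbers were checked for pairing from the correlation of same-numbered deviations, which was 0.126 in SK-OV-3, 0.561 in TOV-21G and -0.137 between the lines. They were taken to pair arrays within a line, and a fit with that block was run beside the unblocked one. Only 1 correlation per line could be had, so the pairing is not certain, and it was decided with the counts of the blocked fit already in view.

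The alternatives were the replicate block, leaving out each array, median scaling, no background correction, normexp with an offset of 50, the values normalized by the authors, no detection filter, detection in all 8 arrays, all probes as themselves, an adjusted p threshold of 0.01, limma with a trend and robust spread, only the 4 arrays of a line, an estimated correlation and fry. A slide block was not run because the sources used here give no slide. The pipeline was tested on simulated data of the same size: in TOV-21G it recovered 14.0% of log2 changes of 1 and 92.2% of log2 changes of 2, and 4.91% of its calls were false. With no simulated change, 0 genes and 0 lists were called in SK-OV-3. However, noise was drawn independently for each gene and array from the fitted spread, without deviations shared by genes or by same-numbered arrays. The simulation thus checks the pipeline. It says nothing about lists of correlated genes, and the share of false calls in the real arrays may be higher. Detection p-values set the floor, and the number of arrays limits the precision.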

Results

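Expression was measured 72 h after transfection in SK-OV-3 and TOV-21G, both established ovarian carcinoma lines, with 2 control and 2 CSE1L siRNA arrays per line. Between 9206 and 9820 of 24531 probes were detected per array, or 37.5% to 40.0%, and median signals ranged from 156 to 202. Replicates correlated across genes at 0.980 and 0.982 in the SK-OV-3 control and silenced groups, and at 0.979 and 0.972 in those of TOV-21G. The series asked how silencing CSE1L alters expression in each line.

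CSE1L, the export receptor that returns importin alpha from the nucleus to the cytoplasm, fell by 4.08 on the log2 scale in TOV-21G (SE 0.63, 16.9-fold, n = 2 arrays per group, limma adjusted p = 0.0257). Its mean log2 intensity there was 12.34 ± 0.97 (SD, n = 2) in control cells and 8.26 ± 0.76 (SD, n = 2) in silenced cells. In SK-OV-3 it was 12.30 ± 0.37 (SD, n = 2) in control and 9.75 ± 1.08 (SD, n = 2) in silenced cells. That change of -2.55 (SE 0.63) did not pass (limma adjusted p = 0.262), although both silenced arrays, at 10.51 and 8.99, lay below both control arrays, at 12.04 and 12.56. The mean of both lines fell by 3.31 (SE 0.44, limma adjusted p = 0.0287), and the changes in the lines did not differ past the threshold (-1.53, adjusted p = 0.620). The TOV-21G call for CSE1L was lost with only the 4 arrays of that line (adjusted p = 0.0968) and without TOV-21G control replicate 1 (0.162), TOV-21G control replicate 2 (0.0767) or TOV-21G silenced replicate 2 (0.112). The call for the mean was lost without any 1 array (0.0541 to 0.113) except TOV-21G silenced replicate 1.

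RASSF1, a gene of the Ras association domain family, rose in both lines. In SK-OV-3 it rose by 2.68 (SE 0.25, 6.40-fold, limma adjusted p = 0.0465), from 8.89 and 8.80 in control to 11.21 and 11.84 in silenced arrays. In TOV-21G it rose by 2.37 (SE 0.25, 5.18-fold, limma adjusted p = 0.0149), from 9.34 and 9.36 to 11.72 and 11.72. The mean of both lines rose by 2.53 (SE 0.17, 5.76-fold, limma adjusted p = 0.00533), and the difference between the lines was -0.31 (adjusted p = 0.832). The other 2 detected RASSF1 probes changed by 2.67 and 2.69 in SK-OV-3 and by 2.17 and 2.22 in TOV-21G, with adjusted p over all probes of 0.127, 0.0578, 0.0441 and 0.0209 in that order. By annotation the first of these is for another RASSF1 transcript than the probe used, and the second for the same transcript. The last of the 4 RASSF1 probes, for yet another transcript, was detected on no array. Over the alternatives the RASSF1 change ranged from 2.30 to 2.98 in SK-OV-3, 2.08 to 2.39 in TOV-21G and 2.19 to 2.67 for the mean. The SK-OV-3 call was lost with the replicate block (adjusted p = 0.118), all probes as themselves (0.0557), no detection filter (0.0506) or only that line's 4 arrays (0.257), and without any 1 of the 8 arrays (0.0764 to 0.198). The TOV-21G call was lost with only that line's 4 arrays (0.0941) and without TOV-21G control replicate 1 (0.103), TOV-21G control replicate 2 (0.0767) or TOV-21G silenced replicate 2 (0.0748). The call for the mean was lost without SK-OV-3 control replicate 1 (0.0522) or SK-OV-3 control replicate 2 (0.0698).

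**Figure D1:**
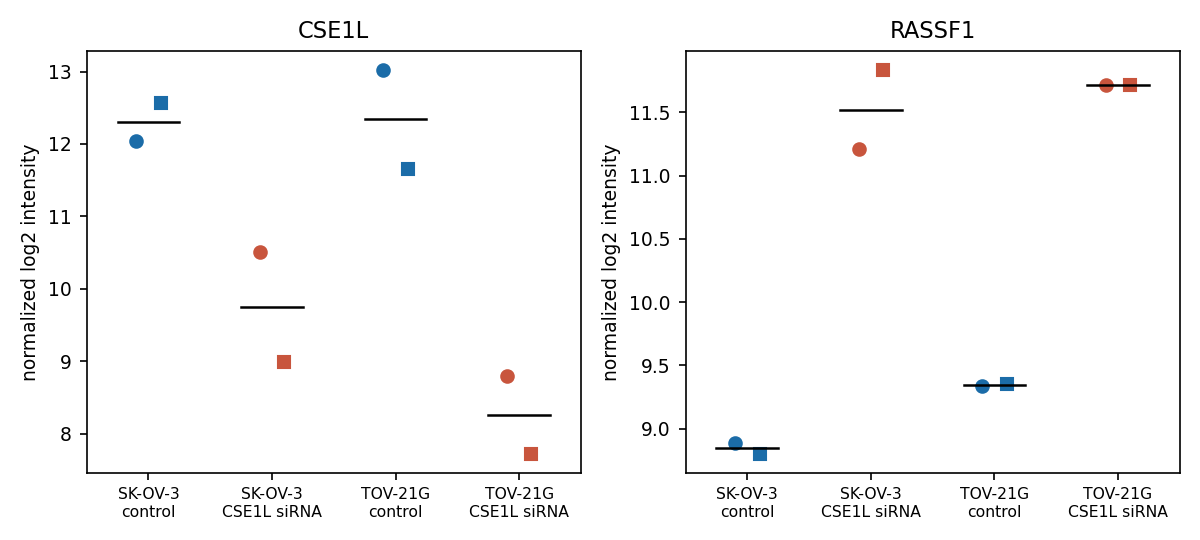
Normalized log2 intensity (y) of CSE1L and RASSF1 in each of the 8 arrays by group (x), with control siRNA in blue, CSE1L siRNA in red, replicate 1 as circles, replicate 2 as squares and group means as bars. Silenced arrays lie below control arrays for CSE1L (means 9.75 against 12.30 in SK-OV-3 and 8.26 against 12.34 in TOV-21G) and above them for RASSF1 in both lines.

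The importin alpha genes encode the cargo that CSE1L exports. KPNA4 rose by 1.29 in TOV-21G (SE 0.27, 2.44-fold, limma adjusted p = 0.0471) and by 1.0 in the mean of both lines (SE 0.19, adjusted p = 0.0463). Its SK-OV-3 change of 0.72 did not pass (adjusted p = 0.433). Both KPNA4 calls were lost with median scaling (adjusted p = 0.0627 and 0.0666), with no detection filter (0.0625 and 0.0575) and without any 1 of the 8 arrays (0.0560 to 0.203 and 0.0723 to 0.151). The TOV-21G call was also lost with only that line's 4 arrays (0.0968). KPNA6 changed by 0.51 in TOV-21G (adjusted p = 0.238) and by -0.39 in SK-OV-3 (adjusted p = 0.608). The probes for KPNA2, KPNA3 and KPNA5 did not pass the detection filter, and KPNA1 was not analysed here. Among the 25 tested nuclear transport receptors, XPO7, an exportin, fell by 1.04 in TOV-21G (adjusted p = 0.0348) and KPNA4 was the 1 member that rose. The list as a whole did not pass camera (median -0.18, adjusted p = 0.807).

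In TOV-21G, genes of cell division fell after silencing, with 19 of 38 tested mitosis genes called, although the list's shift was not called by camera with an estimated correlation (adjusted p = 0.306). Among them were CENPA, the centromeric histone (-2.50, SE 0.27, limma adjusted p = 0.0149), and TOP2A, the topoisomerase that untangles sister chromatids (-2.44, SE 0.32, adjusted p = 0.0203). CDC45, part of the replicative helicase, fell by 2.77 (SE 0.47, adjusted p = 0.0285), and RRM2, a ribonucleotide reductase subunit, fell by 2.41 (SE 0.27, adjusted p = 0.0149). The pocket protein gene RBL1 was at least 4.71-fold lower (adjusted p = 0.0149), the peptide hormone gene UCN2 at least 3.64-fold lower (0.0149), and C6orf58 at least 2.99-fold lower (0.0149). ACOT11, an acyl-CoA thioesterase, fell by 3.26 (SE 0.51, adjusted p = 0.0257), and the cytokine TNF fell by 2.51 (SE 0.38, adjusted p = 0.0257). Genes that rose included the receptor kinase GRK4 (at least 3.45-fold, adjusted p = 0.0257), the glutathione transferase GSTM3 (at least 2.12-fold, 0.0214) and the calcium pump regulator SLN (at least 1.34-fold, 0.0149). Others were the lysosomal protease CTSF (1.77, adjusted p = 0.0385), the AP-1 component FOSB (1.74, 0.0261), MACROD1 (1.86, 0.0230), and KLHL28 (1.75, 0.0164). All 16 genes named here lost their call with only the 4 arrays of the line (adjusted p = 0.0941 to 0.116). Of the 15 tested, all lost it without TOV-21G control replicate 1 (0.103 to 0.20) or TOV-21G silenced replicate 2 (0.0748 to 0.15), and all but UCN2 without TOV-21G control replicate 2 (0.0767 to 0.125). Without TOV-21G silenced replicate 1, CTSF, FOSB, GRK4, MACROD1 and TNF lost it (0.0530 to 0.0922). CDC45 lost its call without any 1 of the SK-OV-3 arrays (0.0516 to 0.0571). CTSF lost it without SK-OV-3 silenced replicate 1 (0.0625) or SK-OV-3 silenced replicate 2 (0.0593) and with no filter (0.0531). ACOT11 and CDC45 were each detected on only 1 of the 2 silenced TOV-21G arrays, and FOSB on 1 of the 2 control arrays. Their changes thus include signal below detection. ACOT11, CDC45 and FOSB changed by -1.96, -1.81 and 0.92 with no background correction and by -1.75, -1.62 and 0.84 on the values normalized by the authors, where MACROD1 changed by 1.22. FOSB changed by 1.14 with normexp and an offset of 50. RBL1, UCN2, C6orf58, GRK4, GSTM3 and SLN also moved toward 0 by over 1.5 times with no background correction and on the authors' values, as did all of them except RBL1 with the offset of 50. Over the alternatives their log2 changes came as near to 0 as -1.32, -1.44, -1.22, 1.09, 0.82 and 0.75 in that order. The bounds on that scale were -2.24, -1.86, -1.58, 1.78, 1.09 and 0.42, so all but that of SLN hold for the main processing only. In all, limma called 297 of 9377 genes, 102 higher and 195 lower, and 291 of them had a fitted change of at least 2-fold. With the replicate block it called 590 (237 higher, 353 lower), of which 291 were among the 297, with median scaling 67 higher and 230 lower, and with only the 4 arrays of the line 0. At an unadjusted p under 0.05 the counts were 1862 with all arrays and 1638 with those 4. The count was 0 without TOV-21G control replicate 1 or TOV-21G silenced replicate 2 (1211 and 1449 at an unadjusted p under 0.05), 1 without TOV-21G control replicate 2 and 142 without TOV-21G silenced replicate 1. It was 182, 173, 131 and 132 without SK-OV-3 control replicate 1, SK-OV-3 control replicate 2, SK-OV-3 silenced replicate 1 and SK-OV-3 silenced replicate 2.

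All 38 tested mitosis and G2/M genes lay below 0 in TOV-21G, with a median of -1.60. Of these 19 fell and 19 did not pass over all genes, and 35 fell when adjusted over the list alone (camera adjusted p = 6.82e-27, and adjusted p = 0.306 with an estimated correlation). They included the mitotic kinase AURKB (-2.31, SE 0.36) and the kinetochore gene SPC24 (-2.30, SE 0.34). Of the 41 DNA replication and G1/S genes, 40 lay below 0 with a median of -1.19. Over all genes 17 fell, among them the origin gene ORC1 (-2.15) and the transcription factor E2F2 (-2.15). Adjusted over the list alone 31 fell (camera adjusted p = 8.41e-23, and adjusted p = 0.306 with an estimated correlation). DNA damage repair genes had a median of -0.51, or -0.47 with undetected members at their bound. EXO1 (-2.28), RAD51AP1 (-1.84), BARD1 (-1.74) and XRCC3 (-1.39) fell, the 4 of 31 called over all genes. There were 8 that fell when adjusted over the list alone (camera adjusted p = 2.7e-05, adjusted p = 0.346 with an estimated correlation, and 0.0638 by fry). The DNA repair median was -0.86 without TOV-21G silenced replicate 1, -0.25 without TOV-21G silenced replicate 2 and -0.32 without TOV-21G control replicate 1. It was -0.34 with no background correction and -0.27 on the values normalized by the authors.

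Smaller shifts in TOV-21G went in both directions. Nucleoporin genes, of the nuclear pore, had a median of -0.43, with NUP210 (-1.38) and NUP35 (-1.03) not past the threshold. Of 26, 0 were called over all genes and 6 lower when adjusted over the list alone (camera adjusted p = 2.58e-04, and adjusted p = 0.306 with an estimated correlation). Spliceosome genes had a median of -0.30, with 1 of 44 lower, HNRNPC (-0.98, adjusted p = 0.0405), and 2 when adjusted over the list alone (camera adjusted p = 0.00196, adjusted p = 0.676 with an estimated correlation, and 0.181 by fry). NF-kB targets had a median of -0.45, or -0.33 with undetected members at their bound. Of 23, TNF and the cytokine LTB (at least 1.26-fold lower, adjusted p = 0.0185) passed, and 5 were lower when adjusted over the list alone (camera adjusted p = 0.00298, and adjusted p = 0.306 with an estimated correlation). Epithelial junction genes had a median of -0.24. CDH1, which encodes E-cadherin, was at least 2.44-fold lower (adjusted p = 0.0176). It was the 1 of 24 called over all genes or adjusted over the list alone (camera adjusted p = 0.0372, adjusted p = 0.356 with an estimated correlation, 0.118 by fry and 0.0657 with the replicate block). The epithelial median was -0.07 and not called with detection in all 8 arrays (adjusted p = 0.395) or with no filter (0.102), and -0.09 and not called with all probes as themselves (0.115). It was -0.15 with normexp and an offset of 50, -0.11 with no background correction and -0.10 on the values normalized by the authors. Lysosome and autophagy genes had a median of 0.34 with 35 of 39 above 0. CTSF and the autophagosome gene MAP1LC3B (1.46) rose, and 2 members were higher adjusted over the list alone (camera adjusted p = 8.74e-05, and adjusted p = 0.306 with an estimated correlation). Of 27 p53 targets 21 lay above 0 with a median of 0.34, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.306 with an estimated correlation, and 0.0686 by fry). CDKN1A entered this list by 1 probe (0.29), while its other detected probe changed by 1.99 (limma adjusted p over all probes 0.0266). Fatty acid synthesis genes had a median of 0.45, with 0 of 16 called over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.306 with an estimated correlation). Cholesterol synthesis genes had a median of 0.40. HMGCS1, the synthase that feeds the mevalonate pathway, rose by 1.14 (adjusted p = 0.0406), the 1 of 14 called, and 3 were higher adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.334 with an estimated correlation). With detection in all 8 arrays the NF-kB and p53 calls were lost (adjusted p = 0.0878 for each). With no filter the medians were -0.22 for NF-kB targets and 0.23 for cholesterol genes, and the NF-kB median was -0.24 with all probes as themselves and -0.29 with no background correction. fry called 8 of the 41 lists. Without TOV-21G control replicate 1 the calls were lost for the cholesterol (adjusted p = 0.0853), epithelial (0.294), NF-kB (0.0531), p53 (0.159) and spliceosome lists (0.211, median -0.19). Without TOV-21G silenced replicate 2 they were lost for the cholesterol (0.0721), epithelial (0.0690), p53 (0.0690) and spliceosome lists (0.266, median -0.12). The fatty acid and epithelial calls were lost without TOV-21G control replicate 2 (0.0708 and 0.0807) or TOV-21G silenced replicate 1 (0.0690 and 0.106). AURKB, SPC24, ORC1, E2F2, EXO1, RAD51AP1, BARD1, XRCC3, XPO7, HNRNPC, LTB, CDH1, MAP1LC3B and HMGCS1 all lost their calls with only the 4 arrays of the line (adjusted p = 0.0968 to 0.131) or without TOV-21G silenced replicate 2 (0.0794 to 0.153). The 12 of them that were tested, all but LTB and CDH1, lost them without TOV-21G control replicate 1 (0.14 to 0.237) or TOV-21G control replicate 2 (0.0767 to 0.153). XPO7, EXO1, BARD1, HNRNPC and HMGCS1 lost theirs without any 1 of the SK-OV-3 arrays (0.0501 to 0.0755), RAD51AP1 without SK-OV-3 silenced replicate 1 (0.0632) or SK-OV-3 silenced replicate 2 (0.0624), and MAP1LC3B without SK-OV-3 control replicate 1 (0.0608) or SK-OV-3 control replicate 2 (0.0618). Without TOV-21G silenced replicate 1 the calls were lost for XPO7, RAD51AP1, HNRNPC, MAP1LC3B and HMGCS1 (0.0610 to 0.124), with median scaling for HNRNPC, MAP1LC3B and HMGCS1 (0.0627 to 0.115), and with no filter for EXO1 (0.0531) and HMGCS1 (0.0506). EXO1 changed by -1.52 with normexp and an offset of 50, -1.23 with no background correction and -1.08 on the values normalized by the authors, where RAD51AP1 changed by -1.14. LTB and CDH1 also moved toward 0 by over 1.5 times under these 3, and the LTB call was lost on the authors' values (0.0610). CDH1 changed by -1.12, -0.88 and -0.79 on the log2 scale under them, each short of its 2.44-fold bound.

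**Figure D2:**
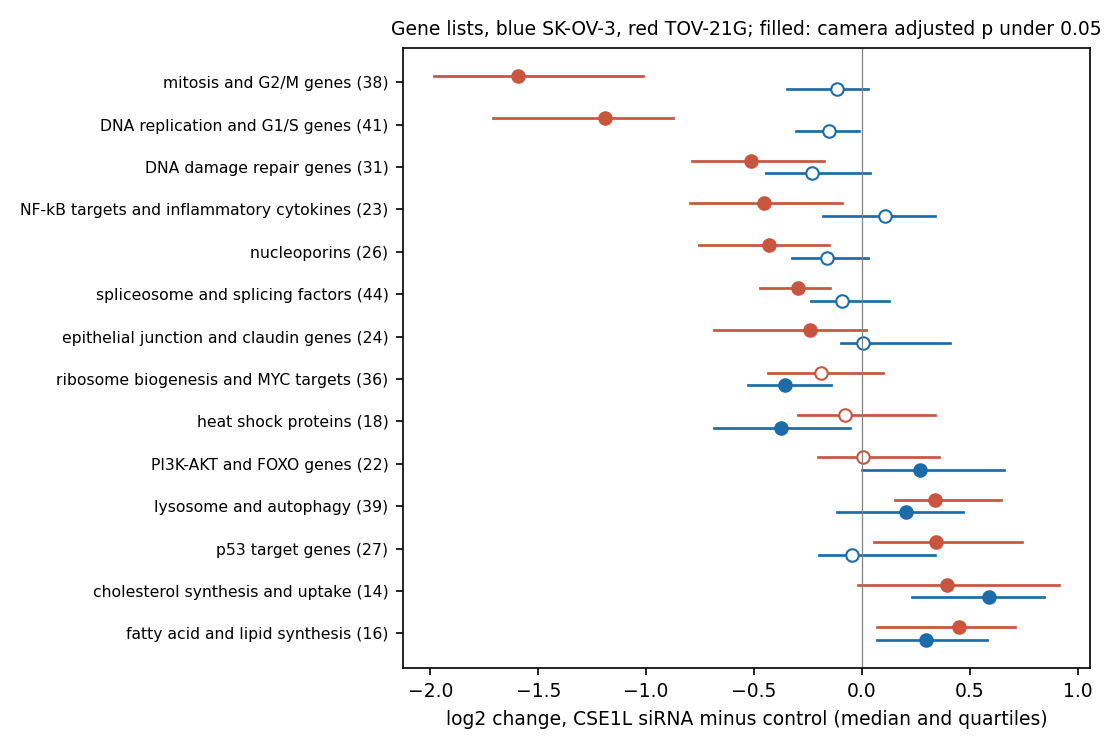
Median (points) and quartiles (lines) of the log2 change after CSE1L silencing (x) for 14 gene lists (y, tested members in brackets), with SK-OV-3 in blue, TOV-21G in red and filled points where the camera adjusted p was under 0.05 at the preset correlation. The TOV-21G medians reach -1.60 for mitosis and -1.19 for DNA replication, against -0.12 and -0.15 in SK-OV-3.

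In SK-OV-3, RASSF1 was the 1 gene that passed. The values nearest to the threshold included higher CPA4, a carboxypeptidase (2.25, SE 0.28, limma adjusted p = 0.0816), MXD4, a MAX partner that opposes MYC (1.75, SE 0.20, 0.0816), and the basal keratin KRT5 (2.42, SE 0.32, 0.0904), none of which passed. Lower values that did not pass included ETV5, an ETS transcription factor (-1.63, SE 0.22, adjusted p = 0.0904), ADGRG2 (-1.31, 0.131), ACOX2, a peroxisomal oxidase (at least 1.76-fold, 0.0816), and VWA8 (at least 1.86-fold, 0.0816). Over the alternatives CPA4, MXD4 and ETV5 passed in 5 each, KRT5 and ACOX2 in 3 each, and ADGRG2 and VWA8 in 0. The change nearest to 0 was 1.54 for KRT5 among the higher genes. Among the lower genes it was -0.58 for VWA8, short of its log2 bound of -0.90, followed by -0.62 for ADGRG2. In the main fit limma called 1 of 9377 genes, with 940 at an unadjusted p under 0.05, where 469 would be given by chance. The count was 0 without any 1 of the 8 arrays (634 to 994 at an unadjusted p under 0.05) and with the replicate block (1439), 2 with median scaling, 13 with the values normalized by the authors and 11 with a trend and robust spread.

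Gene lists in SK-OV-3 moved by small amounts. Ribosome biogenesis and MYC target genes had a median of -0.36 with 32 of 36 below 0, including RRP9 (-1.10), RRP12 (-0.80) and NOP16 (-0.80). Of these 0 passed over all genes or adjusted over the list alone (camera adjusted p = 4.25e-05, and adjusted p = 0.626 with an estimated correlation). Cholesterol synthesis genes had a median of 0.59 with 12 of 14 above 0, and 0 passed over all genes. Adjusted over the list alone 6 were higher and 1 lower, with MVK at 1.03, HMGCS1 at 1.01, DHCR7 at 0.92 and EBP at -1.09 (camera adjusted p = 6.66e-04, and adjusted p = 0.50 with an estimated correlation). Heat shock genes had a median of -0.38, with HSPA1B at -1.26, DNAJB1 at -1.02 and HSPH1 at -1.01. Of 18, 0 passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.556 with an estimated correlation). Fatty acid synthesis genes had a median of 0.30 (FADS2 0.95, SREBF1 0.87, SCD 0.73). PI3K-AKT and FOXO genes had a median of 0.27, or 0.13 with an undetected member at its bound (KLF6 1.49, FOXO1 0.83), and lysosome genes 0.20 (CTSF 1.37, GABARAPL1 1.15, CTSH 0.83). None of the members of these 3 lists passed over all genes, and 2 PI3K-AKT and FOXO genes and 0 of the fatty acid or lysosome genes were higher adjusted over the list alone. camera gave adjusted p = 0.0208, 0.0415 and 0.0408 for the fatty acid, lysosome and PI3K-AKT lists. With an estimated correlation these had adjusted p = 0.50, 0.556 and 0.50, and fry called 0 of the 41 lists, with 9 at an unadjusted camera p under 0.05. With no filter the PI3K-AKT (median 0.06, adjusted p = 0.272) and lysosome calls (0.0607) were lost and the cholesterol median was 0.29, and with all probes as themselves the fatty acid call was lost (0.108). Median scaling, which moved the median of all genes in SK-OV-3 to -0.15, gave medians of -0.54 for ribosome biogenesis, 0.13 for fatty acid, 0.09 for PI3K-AKT and 0.05 for lysosome genes, with the lysosome call lost (0.0736). The PI3K-AKT median was 0.18 on the values normalized by the authors. Without SK-OV-3 control replicate 1 the calls were lost for the ribosome biogenesis (median -0.15, adjusted p = 0.185), heat shock (0.176), fatty acid (0.176), PI3K-AKT (0.185) and lysosome lists (0.312). Without SK-OV-3 silenced replicate 2 they were lost for the heat shock (0.162), fatty acid (0.108), PI3K-AKT (0.188) and lysosome lists (0.0605). The lysosome call was also lost without SK-OV-3 silenced replicate 1 (0.142) or TOV-21G silenced replicate 1 (0.0503).

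The mean of both lines asked about the average change over 4 silenced and 4 control arrays, which 1 line alone can carry. RASSF1, CPA4 (1.86, SE 0.20, limma adjusted p = 0.0200) and HMOX1, the haem-degrading oxygenase (1.68, SE 0.28, 0.0344), rose. CTSF (1.57, SE 0.24, 0.0317), the histone gene H2BC5 (1.47, SE 0.21, 0.0305) and FOSB (1.44, SE 0.20, 0.0287) also rose. SLN was detected on all silenced arrays and on no control array (adjusted p = 0.0159). Of these genes only RASSF1 passed in SK-OV-3 alone, where CPA4 changed by 2.25, HMOX1 by 1.78, H2BC5 by 1.5, CTSF by 1.37 and FOSB by 1.14. Genes that fell included AURKA, a mitotic kinase (-1.54, SE 0.14, adjusted p = 0.0160), RRM2 (-1.54, SE 0.19, 0.0281) and INAVA (-1.71, SE 0.31, 0.0423, and 0.0512 with the replicate block). In SK-OV-3 alone these changed by -0.81 (adjusted p = 0.262), -0.67 (0.463) and -1.54 (0.300), none past the threshold. UCN2 passed for the mean (adjusted p = 0.0287) with a change of -0.07 in SK-OV-3 (0.961). TERT, the catalytic subunit of telomerase, was detected on both control arrays of each line and on no silenced array (adjusted p = 0.0330). The cohesin gene SMC1A was detected on all arrays except those of silenced TOV-21G cells (adjusted p = 0.0326). Apart from RASSF1, all 12 genes named for the mean lost their call without SK-OV-3 control replicate 1 (0.0522 to 0.0990), SK-OV-3 control replicate 2 (0.0698 to 0.104), SK-OV-3 silenced replicate 2 (0.0710 to 0.133), TOV-21G control replicate 1 (0.0716 to 0.135) or TOV-21G silenced replicate 2 (0.0659 to 0.10). All but UCN2 lost it without TOV-21G control replicate 2 (0.0522 to 0.107), and all but AURKA, CPA4, SLN and SMC1A without SK-OV-3 silenced replicate 1 (0.0541 to 0.0919). Without TOV-21G silenced replicate 1 it was lost for CTSF, INAVA, SMC1A and TERT (0.0532 to 0.0574). INAVA also lost it with no filter (0.0571) and TERT on the authors' values (0.0602). FOSB changed by 0.96 with normexp and an offset of 50, 0.78 with no background correction and 0.69 on the authors' values, and SLN, SMC1A, TERT and UCN2 also moved toward 0 by over 1.5 times under these 3. limma called 201 genes, 86 higher and 115 lower, of which 123 had a fitted change of at least 2-fold and 178 had the same sign in all 4 same-numbered comparisons. With the replicate block it called 518 (243 higher, 275 lower, 199 of them among the 201), and with median scaling 39 higher and 152 lower. That scaling moved the median of all genes to -0.11. The count was 0 without SK-OV-3 control replicate 1 or SK-OV-3 control replicate 2 (1675 and 1687 at an unadjusted p under 0.05), 7 without SK-OV-3 silenced replicate 1 and 2 without SK-OV-3 silenced replicate 2. It was 1 without TOV-21G control replicate 1, 3 without TOV-21G control replicate 2, 100 without TOV-21G silenced replicate 1 and 1 without TOV-21G silenced replicate 2.

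In the mean of both lines, cholesterol synthesis genes had a median of 0.59. HMGCS1 (1.08, adjusted p = 0.0317) and DHCR7 (0.78, 0.0488) rose, and 9 of 14 were higher and 1 lower adjusted over the list alone (camera adjusted p = 7.96e-04, and adjusted p = 0.361 with an estimated correlation). Fatty acid genes had a median of 0.42. The desaturase SCD rose (0.86, adjusted p = 0.0423), and 8 of 16 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.361 with an estimated correlation). Lysosome genes had a median of 0.27, with CTSF and MAP1LC3B (1.0, adjusted p = 0.0463) called and 6 of 39 called adjusted over the list alone (camera adjusted p = 1.04e-04, and adjusted p = 0.361 with an estimated correlation). Mitosis genes had a median of -0.85, with 12 of 38 lower, or 29 adjusted over the list alone, against medians of -1.60 in TOV-21G and -0.12 in SK-OV-3. DNA replication genes had a median of -0.69, with 5 of 41 lower, or 29 adjusted over the list alone, against -1.19 in TOV-21G and -0.15 in SK-OV-3. camera gave adjusted p = 9.53e-19 and 1.04e-16 (adjusted p = 0.447 for each with an estimated correlation). DNA repair genes (median -0.42, 2 of 31 lower, 4 adjusted over the list alone, camera adjusted p = 4.57e-05), ribosome biogenesis genes (-0.27, 0 and 0, 5.22e-04), nucleoporins (-0.26, 0 and 3, 7.96e-04) and spliceosome genes (-0.18, 0 and 0, 0.0125) were also lower. Their adjusted p with an estimated correlation were 0.447, 0.501, 0.447 and 0.692, and by fry 0.0815, 0.125, 0.0504 and 0.269, where fry called 6 of the 41 lists. With no filter the medians were 0.22 for cholesterol, 0.27 for fatty acid and -0.17 for DNA repair genes. The DNA repair median was also -0.23 with normexp and an offset of 50, -0.19 with no background correction, -0.14 on the values normalized by the authors, -0.27 without TOV-21G control replicate 1 and -0.23 without TOV-21G silenced replicate 2. Median scaling gave 0.28 for fatty acid, 0.17 for lysosome, -0.40 for nucleoporin and -0.29 for spliceosome genes. The spliceosome median was -0.27 without TOV-21G silenced replicate 1. The spliceosome call was lost without SK-OV-3 silenced replicate 1 (adjusted p = 0.0560), TOV-21G control replicate 1 (median -0.11, 0.25) or TOV-21G silenced replicate 2 (median -0.05, 0.283). HMGCS1, DHCR7, SCD and MAP1LC3B lost their calls without any 1 of the 8 arrays (0.0532 to 0.165) and with median scaling (0.0505 to 0.171), DHCR7 and MAP1LC3B with no filter (0.0592 and 0.0578), and DHCR7 with all probes as themselves (0.0527).

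The difference between lines asked which genes changed differently in TOV-21G than in SK-OV-3, with the sign of each change kept. A value away from 0 can thus come from opposite changes. Mitosis genes had a median difference of -1.36, with 38 of 38 below 0, and DNA replication genes -1.16, with 40 of 41 below 0. Of these, 25 and 19 members were lower when adjusted over the list alone, and 0 over all genes (camera adjusted p = 1.55e-24 and 2.28e-18, and adjusted p = 0.455 for each with an estimated correlation). Epithelial junction genes (-0.33, camera adjusted p = 0.00329), NF-kB targets (-0.42, 0.00613), DNA repair genes (-0.41, 0.0214), nucleoporins (-0.30, 0.0396) and spliceosome genes (-0.25, 0.0396) also had lower changes in TOV-21G. With an estimated correlation they had adjusted p = 0.455, 0.455, 0.693, 0.537 and 0.882. fry called 0 of the 41 lists, and 13 had an unadjusted camera p under 0.05. Named genes detected on all 8 arrays, none of which passed, were TRIM47 (-2.79), OVOL2 (-2.62) and TRIM6 (-2.49) below 0, each with limma adjusted p = 0.165, and CHPF (1.80, 0.172) above 0. In that order they changed by 1.08, 0.61, 0.45 and -0.68 in SK-OV-3, none past the threshold there, and by -1.71, -2.01, -2.03 and 1.12 in TOV-21G. Over the alternatives the difference passed in 4 for TRIM47, 3 for OVOL2, 3 for TRIM6 and 0 for CHPF. RBL1, CDH1 and KDM5C also had adjusted p = 0.165, and no fold is given for them because each was undetected on both arrays of at least 1 group. limma called 0 genes, with 948 at an unadjusted p under 0.05, and limma called 11 with a trend and robust spread and 10 on the values normalized by the authors. With detection in all 8 arrays the epithelial (adjusted p = 0.0897) and NF-kB calls (0.105) were lost, and with median scaling the nucleoporin (median -0.17, 0.0997) and spliceosome calls (-0.13, 0.122). With no filter the medians were -0.19 for DNA repair and -0.22 for epithelial genes. Without TOV-21G control replicate 1 the calls were lost for all but the mitosis and DNA replication lists (adjusted p = 0.0829 to 0.486), with a spliceosome median of -0.10. Those for the DNA repair, nucleoporin and spliceosome lists were also lost without TOV-21G silenced replicate 2 (0.198, 0.291 and 0.615) or SK-OV-3 silenced replicate 2 (0.0919, 0.113 and 0.144). Without TOV-21G silenced replicate 2 the DNA repair median was -0.22 and the spliceosome median -0.05, and without SK-OV-3 silenced replicate 2 the spliceosome median was -0.16. The DNA repair and nucleoporin calls were lost without SK-OV-3 control replicate 2 (0.0696 and 0.0923), and that for the spliceosome list without SK-OV-3 control replicate 1 (0.121). Without TOV-21G silenced replicate 1 the medians were -0.71 for DNA repair and -0.40 for spliceosome genes, and without TOV-21G control replicate 2 the spliceosome median was -0.38.

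**Figure D3:**
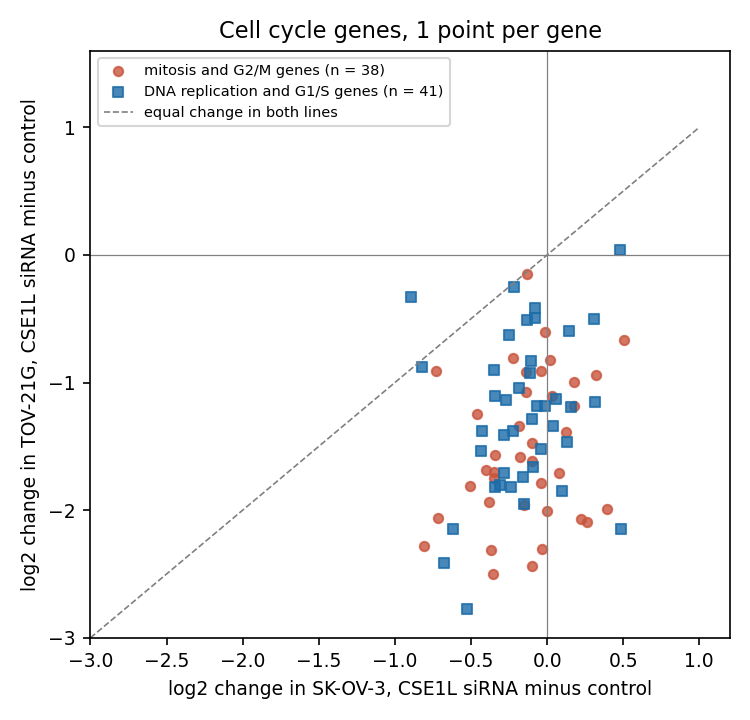
Log2 change after CSE1L silencing in SK-OV-3 (x) and TOV-21G (y), 1 point per gene, for 38 mitosis genes (red circles) and 41 DNA replication genes (blue squares), with a dashed line of equal change. Of the 79 genes, 78 had a lower change in TOV-21G than in SK-OV-3.

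The changes in both lines correlated weakly across genes (Pearson r 0.281, Spearman rho 0.287, 9377 genes, which are not independent replicates), and 60.8% of genes had the same sign. Between single experiments, r was 0.290 within SK-OV-3, 0.668 within TOV-21G and 0.182 to 0.221 between the lines. The r of 0.281 is from changes averaged over 2 experiments, so it is not to be set against these. The low r within SK-OV-3 limits what could be seen between the lines. A weak r between them does not by itself show unlike responses. Of the TOV-21G calls, 84 of 102 higher and 151 of 195 lower genes had the same sign in SK-OV-3. In SK-OV-3, 38 of the higher calls were higher at an unadjusted p under 0.05, where 5.19 would be given by independent lists, and 36 of the lower calls were lower, where 9.63 would be. In the opposite direction these counts were 1 and 2. No test is given for this overlap, because both lines share each gene's estimate of spread.

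In cells given the scrambled siRNA, the lines differed widely. No cells without transfection were measured, so unequal responses to it cannot be told from an untreated baseline. In control cells the inflammatory cytokine IL6 was at least 267-fold higher in TOV-21G than in SK-OV-3, and the stress cytokine GDF15 at least 120.5-fold. The lipid carrier APOE was at least 103-fold higher, the chemokine CCL20 at least 93.6-fold, and the chemokine receptor CXCR4 at least 42.7-fold. UQCRH, a respiratory complex III subunit, was at least 258-fold higher (limma adjusted p = 7.18e-07). Lower in TOV-21G were PPP1R1B, a phosphatase inhibitor (at least 172-fold), FOLR1, the folate receptor (at least 52.5-fold), and the homeobox gene HOXB2 (at least 58.1-fold). The bounds in this paragraph hold for the main processing only. Over the alternatives the log2 difference was as small as 6.64 for IL6, 5.69 for GDF15, 5.59 for APOE and 5.44 for CCL20. It was as small as 4.57 for CXCR4 and 7.07 for UQCRH. It came as near to 0 as -6.43 for PPP1R1B, -4.45 for FOLR1 and -4.84 for HOXB2. In that order the log2 bounds were 8.06, 6.91, 6.69, 6.55, 5.42, 8.01, -7.43, -5.71 and -5.86. On the values normalized by the authors CXCR4, HOXB2, TNF and IL32 moved toward 0 by over 1.5 times and stayed past the threshold. NF-kB targets had a median difference of 2.27, or 1.94 with undetected members at their bound, with 16 of 23 higher and 2 lower, or 17 and 2 adjusted over the list alone. The NF-kB median was 0.74 with no filter and 1.41 on the values normalized by the authors. Those higher included TNF (at least 40.2-fold) and IL32 (at least 27.6-fold). p53 targets had a median of 1.32, or 1.13 with bounds, with 16 of 27 higher, or 17 adjusted over the list alone, including the cell cycle inhibitor CDKN1A (5.68, SE 0.51, adjusted p = 9.79e-05). The p53 median was 0.43 with no filter, 0.73 with detection in all 8 arrays, 0.80 with no background correction and 0.77 on the values normalized by the authors. Clear cell carcinoma genes had a median of 1.12, with 7 of 11 higher and 1 lower, or 8 and 1 adjusted over the list alone, including FXYD2 (6.19) and SPP1 (2.05). camera gave adjusted p = 6.94e-07, 2.09e-04 and 0.0069, with adjusted p = 0.225, 0.225 and 0.298 with an estimated correlation, and the clear cell median was 0.68 with no filter and its call was lost with detection required in all 8 arrays (0.156). limma called 3166 genes between the control lines, 1601 higher and 1565 lower in TOV-21G, and 2441 had a fitted difference of at least 2-fold.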

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

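The tests of knockdown strength, of normalization and of the RASSF1 probes were chosen only after the results they concern were seen. For each of the 7 gene lists given here, the change in TOV-21G was called different from that in SK-OV-3 by camera at its preset correlation. That is a test of the difference itself. None of the lists passed with an estimated correlation (adjusted p 0.455 to 0.882) or by fry (adjusted p 0.185 to 0.558). The median differences, TOV-21G minus SK-OV-3, were -1.36 for mitosis genes, -1.16 for DNA replication genes, -0.33 for epithelial junction genes, -0.42 for NF-kB targets, -0.41 for DNA repair genes, -0.30 for nucleoporins and -0.25 for spliceosome genes. Without TOV-21G control replicate 1 only 2 of the lists were called.

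For mitosis and DNA replication genes, a weaker knockdown in SK-OV-3 would give a like change per unit of CSE1L fall in both lines. For mitosis genes the ratio of the list's median change to that of CSE1L was at most 0.0486 in SK-OV-3 and at least 0.313 in TOV-21G, which argues against a proportional response, though not against a response that needs CSE1L to fall below some level. For DNA replication genes the highest SK-OV-3 ratio, 0.262, lay near the lowest in TOV-21G, 0.263, while in the other SK-OV-3 comparison CSE1L fell by 3.58 and the list changed by 0.11 (ratio -0.03), so knockdown strength and line cannot be told apart there with 2 comparisons per line. Normalization as the whole cause is argued against by median differences that stayed at or below -1.14 and -0.93 under 4 other corrections or sources, and a floor in SK-OV-3 by the 94.7% and 97.6% of members detected on both its control arrays. A difference between the lines themselves, such as their p53 status, stays open and untested for these lists.

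The rise of RASSF1 in both lines was seen with all 3 detected probes, which argues against a single probe that binds another transcript. A change of the whole chromosomal neighbourhood is argued against by the median change of its 10 nearest tested genes, 0.0896, of which HYAL3 alone passed (0.86, adjusted p = 0.0423), a call lost with median scaling and without any 1 of the 8 arrays. An effect of the siRNA on RASSF1 apart from CSE1L was not tested and stays open.

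For the mean of both lines, chance was tested over splits of the 8 arrays into 4 and 4, 34 of which allowed a fit. The real one called 201 genes and the highest other 1, so that 1 of 34 gave as many. It called 9 gene lists and the highest other 14, and 9 of 34 gave as many. However, 16 of the 34 took unequal numbers of arrays from the lines, which differ in 3166 genes, and so are no measure of chance. The 18 with 2 arrays of each line on each side are too few for a share under 0.05, and the highest other counts among them were 1 gene and 14 lists. So are the 8 that also part all 4 same-numbered pairs, with highest other counts of 0 genes and 14 lists. Others of the 18 called 10, 11, 10 and 14 lists against the real 9, so the list count does not set the real split apart. The adjusted p-values of camera at the preset correlation may thus be too small, here and in the other comparisons. Some of the 18 still part the silenced from the control arrays of 1 line, so they are not free of an effect of silencing.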

How the results depend on the processing

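The alternatives were planned, but the experiment numbers were taken to pair the arrays with the counts of the replicate block already in view. No result reversed its direction under any that was run. With 1 array left out the gene counts ranged from 0 to 100 for the mean of both lines, 0 to 182 in TOV-21G, 0 to 0 in SK-OV-3 and for the difference between lines, and 2141 to 3247 between the control lines. The number of lists called ranged from 1 to 9 in SK-OV-3 (1 without SK-OV-3 control replicate 1), 6 to 12 in TOV-21G (6 without TOV-21G control replicate 1), 8 to 11 for the mean and 2 to 10 for the difference (2 without TOV-21G control replicate 1). The correlation between lines ranged from 0.207 to 0.293, and the CSE1L change in TOV-21G from -4.75 to -3.42. A lone array left in a group is assumed to vary like the other groups. For genes named in the silencing comparisons 419 values kept and 236 lost a call over all alternatives, or 99 and 207 with an array left out. Between the control lines 300 kept a call and 0 lost it. Where no call was made, 31 gained one and 281 did not. For lists that were called, 585 kept and 113 lost the call.

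With an adjusted p under 0.01 limma called 1 gene for the mean, 0 in SK-OV-3, 0 in TOV-21G and 1874 between the control lines. With detection in all 8 arrays it called 389 for the mean, 4 in SK-OV-3, 1 for the difference and 1996 between the control lines, and the correlation between lines was 0.349. With a trend and robust spread it called 461 for the mean, 11 in SK-OV-3, 515 in TOV-21G and 11 for the difference. With no background correction it called 464 for the mean, 9 in SK-OV-3, 527 in TOV-21G and 5 for the difference, with 11 lists for the difference and a correlation of 0.319. With normexp and an offset of 50 it called 369 for the mean and 8 in SK-OV-3, with a correlation of 0.307, and on the values normalized by the authors 389 for the mean, 13 in SK-OV-3 and 10 for the difference, with a correlation of 0.332. With the replicate block it called 518 for the mean, 590 in TOV-21G and 0 in SK-OV-3. In SK-OV-3 it called 2 with median scaling, 0 with all probes as themselves, 0 with no filter on dim probes (correlation 0.218) and 0 with only the 4 arrays of the line (943 at an unadjusted p under 0.05). In TOV-21G it called 0 with only the 4 arrays of the line (1638 at an unadjusted p under 0.05), and CSE1L, at -4.08, was then not past the threshold (adjusted p = 0.0968).

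camera with an estimated correlation called 0 lists in SK-OV-3, 0 in TOV-21G, 0 for the mean and 0 for the difference. It also called 0 between the control lines, where limma called 3166 genes. It thus passed no list in any comparison, so a list that did not pass it is not shown to be unmoved. fry called 0 in SK-OV-3, 8 in TOV-21G, 6 for the mean and 0 for the difference. For these changes the cause was not tested. A slide block was not run. Between 37.5% and 40.0% of probes were detected per array, which limits what is seen of dim genes.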

Other observations

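The test of the p53 hypothesis and the choice of the probe values given here were made only after the data were seen.

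Other gene groups did not pass camera in either line. Pro-apoptotic genes had a median change of 0.04 in SK-OV-3 and 0.16 in TOV-21G, and RASSF1 was the 1 of 31 that rose in each, with 2 in SK-OV-3 and 1 in TOV-21G higher adjusted over the list alone. Interferon-stimulated genes, which can respond to siRNA, had a median of 0.10 in SK-OV-3 and -0.07 in TOV-21G; in TOV-21G SP110 rose by 1.32 (adjusted p = 0.0321) and IRF1 fell by 1.11 (0.0401), and 2 of 29 were higher and 4 lower adjusted over the list alone. Oxidative phosphorylation genes had medians of 0.00 and 0.12, and common reference transcripts -0.04 and 0.02. Markers of cell types other than epithelium did not pass as lists: fibroblast and mesothelial markers had medians of 0.04 in SK-OV-3 and -0.18 in TOV-21G, and none of the endothelial genes ENG and CD34 or the leukocyte genes CD14, CD68 and CORO1A passed in either line.

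A probe with no gene symbol in the annotation used here, ILMN_1706238, changed by -1.52 and -3.51 in the SK-OV-3 comparisons and by -4.14 and -4.02 in those of TOV-21G, with a mean of -3.30 (SE 0.34, limma adjusted p = 0.0200). CSE1L changed by -1.53, -3.58, -4.22 and -3.93 in the same comparisons. The probes of CDKN1A disagreed in TOV-21G: the one with the higher mean changed by 0.29 (adjusted p over all probes 0.817) and the other by 1.99 (SE 0.31, 0.0266). In SK-OV-3 the first changed by 0.40, and the other was detected on none of the 4 arrays.

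It is known that SK-OV-3 lacks p53 and TOV-21G keeps it. The hypothesis that p53 targets may rise more in TOV-21G was tested on the difference between the lines, where the list had a median of 0.26 and adjusted p = 0.0676 with camera, and adjusted p = 0.455 with an estimated correlation. CDKN1A entered the list by its probe with the higher mean, which had a difference of -0.12, against 2.28 for the other. Neither passed (limma adjusted p over all probes 0.982 and 0.183). The hypothesis was neither borne out nor excluded.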
